A study of Mus musculus with 23 samples.

How the data were processed

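Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on livers of female C57BL/6 mice, 13 weeks of age, that were wild type or lacked both LXRα and LXRβ (LXRdKO). Per the labels, mice received a daily oral gavage for 14 days of the RXR agonist bexarotene at 100 mg per kg body weight, of the LXR agonist T0901317 at 30 mg per kg, or of vehicle, which was 1% carboxymethylcellulose. The 23 libraries comprise 3 for LXR, 6 for RXR, 2 for PPARα and 12 for RNA polymerase II (RNAPII). Each transcription factor condition has 1 library, and each of the 6 RNAPII groups has 2 libraries that the labels number as replicates. The design text gives 1 animal per condition and the labels do not say that RNAPII replicates came from separate mice, so p-values below measure the spread between these libraries, and how much of it lies between animals is not known. In chr4:52880001-52990000 wild-type control replicate 1 has 5.55% and replicate 2 97.9% of the tag density of the flank, so these 2 libraries do not behave as copies of 1 sample there. No input library was used here.

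The authors deposited, for each library, the positions of mapped tags in build mm9, per the labels. The deposited files list 1 tag per line, and a count here is the number of lines whose tag falls in an interval; a numeric column of the tag files was not read. The authors also deposited peak lists for the 11 transcription factor libraries, 1 list per library, with a score per peak whose scale is not stated and whose lowest value is 10 in each list. The aligner, the peak caller, its threshold and the tag filters are not given in the sources used here. All 11 transcription factor files hold 4663963 tags, so these libraries had been brought to 1 depth before deposit. Tags are 35 bp long in the LXR and PPARα files, 32 bp in the RXR files for vehicle and T0901317, and 34 bp in both RXR files for bexarotene. RNAPII tags are 32 bp long in replicate 1 and 35 bp in replicate 2 of every group. Repeated tags at 1 position and strand make up 0.531% to 2.95% of RNAPII tags in replicate 1 and 0% in replicate 2, 0.700% and 0.479% in the wild-type and LXRdKO RXR bexarotene libraries, and 0% in the other transcription factor libraries. RNAPII depth runs from 5815725 to 11542996 tags.

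Peaks on the main chromosomes were compared by an overlap of at least 1 bp, and chance overlap was taken as the mean over 100 random shifts within chromosomes. Peaks of all lists were merged where they overlapped into 36322 sites. Each site was placed in a class by the LXR lists of the 3 treatments and the wild-type PPARα list, never by RXR tags. Sites with neither peak can come only from the RXR lists or the LXRdKO PPARα list. RXR tags there are thus read at sites picked largely by RXR peaks. Tags were counted within 100 bp of the site centre and scaled so that 1 tag of a transcription factor library counts as 2.14 normalised tags. Ratios between libraries are given per class as the median over sites of log2 with 1 normalised tag added to each value, and as the log2 ratio of summed tags with a 95% exact binomial interval. Shares carry 95% exact Clopper-Pearson intervals and single sites exact Poisson intervals; all of these cover counting error only. No p-value was computed for the transcription factors, because sites are not replicates.

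RNAPII tags were counted in 264198 bins of 10 kb. Gene spans were planned as the unit, with bins where no annotation of mm9 was at hand, and bins were used. After the low-count filter of edgeR 4.0.16 (filterByExpr), 245056 bins were tested with its quasi-likelihood test and TMM scaling, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All 12 libraries entered 1 model with the 6 groups and no replicate term, as fixed before the data were examined. The same model with the replicate number as a term was planned as an alternative. CPM below are scaled by the TMM factors, and 18548 bins with a mean CPM over 4 times the median are called enriched. Fold changes are log2 values with standard errors from the model.

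The replicate number separates 2 sets of libraries that differ in tag length and in repeated tags. The deviations of replicate 1 from the group mean were positively correlated between groups in all 15 pairs of groups, with coefficients of 0.365 to 0.689 across bins, and the first principal component, with 62.5% of the variance, separates the numbers. The replicate number was therefore treated as pairing the libraries; this check and the calls of both models came out of the same run, so the decision rests on the tag lengths, the repeated tags and the correlations. With the block the common dispersion was 0.0373, and without it 0.102. Counting error made up a median of 4.78% of the squared coefficient of variation in enriched bins. The paired fit calls 179 bins for bexarotene and 196 for T0901317 in wild type, where the fit without the block calls 0. Counts of the paired fit stand beside the others, but paired values are not given for every camera set.

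Both models were tested on simulated counts for T0901317 against control in wild type, with changed bins placed among 245056 bins. The counts were drawn from the paired fit, with its replicate effect and dispersions. By construction this favours the model with the replicate term, so the recovery does not show which model suits the data. Without the replicate term, 0 of 67 bins changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 8-fold were recovered. With it, 1, 50 and 66 were recovered, with 3 false calls. The counting of tags at sites recovered 200 of 200 planted windows, and the overlap step 500 of 500.

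The rule for named items, fixed before the data were examined, takes for each RNAPII comparison the 5 bins with the largest change per direction among those past the threshold, and for the site classes the 5 sites with the most tags. It was applied to the paired fit, because the other fit calls no bin. Regions are given as 1-based mm9 coordinates. Gene names are not given, because no annotation of mm9 was used here and the gene table at hand belongs to another assembly. For that reason planned steps on gene lists, gene panels, cell type markers, genes near sites and DR1 or DR4 sequences were not run.

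Sets of enriched bins that hold sites, or that hold the 300 strongest LXR peaks under T0901317 or the 300 strongest PPARα peaks, were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one, adjusted over 9 sets per comparison; these sets were chosen after seeing the data. Alternatives for RNAPII were other size factors, no filter, DESeq2 1.42.0, 1 tag per position and strand, 5 kb bins, only the groups compared, and each library left out. Alternatives for the sites were scaling by tags outside sites, a 400 bp window, 1 tag per position, a minimum of 10 normalised tags, peak centres within 100 bp, the peaks above the median of the authors' score in each list and the 2000 strongest peaks. Only enriched bins, loess offsets, combinations with the block and a 60 bp tag shift were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used.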

Results

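Binding of the nuclear receptors LXR, RXR and PPARα and of RNAPII was mapped in mouse liver in 23 ChIP-seq libraries. LXR is activated by oxysterols and PPARα by fatty acids, and both bind DNA as heterodimers with RXR. LXR was profiled in wild-type liver under vehicle, bexarotene and T0901317, RXR in wild-type and LXRdKO liver under all 3 treatments, and PPARα in both genotypes under vehicle. RNAPII was profiled in both genotypes under all 3 treatments with 2 libraries per group. Each transcription factor library holds 4663963 tags. RNAPII libraries hold, for replicates 1 and 2, 6862006 and 9034300 tags in wild-type control, 6681707 and 11542996 in wild-type bexarotene, 6811275 and 10423563 in wild-type T0901317, 6503250 and 8379621 in LXRdKO control, 6487688 and 9752557 in LXRdKO bexarotene, and 5815725 and 10563400 in LXRdKO T0901317. The share of RNAPII tags in enriched bins ran from 24.0% in replicate 1 to 46.0% in replicate 2 of LXRdKO T0901317, and was 30.1% and 41.6% in wild-type T0901317. LXR was not profiled in LXRdKO liver, so the loss of LXR itself was not measured here.

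The first question was how far LXR, RXR and PPARα share binding sites. Under vehicle most LXR peaks lay on RXR and PPARα peaks: 85.4% of 3771 LXR peaks overlapped an RXR peak (95% interval 84.2% to 86.5%) and 82.0% overlapped a PPARα peak (80.7% to 83.2%), against 0.414% and 0.562% after random shifts. Shifted peaks can land anywhere on a chromosome, so the values after shifts do not allow for regions where peaks of any factor gather. Of 12585 RXR peaks, 67.9% overlapped a PPARα peak and 25.6% an LXR peak. PPARα, with 16005 peaks, was shared with RXR at 53.3% of its peaks and with LXR at 19.4%, and 58.3% of its peaks overlapped an LXR peak of T0901317-treated liver. By class, 54.4% of RXR peaks of wild-type control liver lay at sites with both an LXR and a PPARα peak. A further 14.8% lay at sites with LXR only, 13.4% at sites with PPARα only and 17.3% at sites with neither. An LXR peak under vehicle, bexarotene or T0901317 places a site in an LXR class, so these shares do not describe vehicle alone. Of the same RXR peaks, 25.6% overlapped an LXR peak of vehicle liver, as given above. The overlap depends on how many peaks enter: among the 2000 strongest peaks of each list, 44.5% of LXR peaks overlapped RXR and 38.3% overlapped PPARα.

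The 36322 sites divided into 9672 with LXR and PPARα peaks, 6650 with LXR only, 6295 with PPARα only and 13705 with neither. With the T0901317 LXR list left out, the classes held 4629, 1160, 11338 and 19195 sites in the same order. The LXR-only site with the most tags, chr3:129174215-129174635, had 70.8 normalised LXR tags under vehicle (exact Poisson 95% interval 48.7 to 99.4), 96.5 under T0901317 and 163 RXR tags under T0901317 in wild type. At chr4:144594175-144594665, also LXR only, RXR tags were 32.2 under vehicle and 221 under T0901317 in wild type, and 72.9 and 127 in LXRdKO. The other LXR-only sites named by the rule, chr6:101168995-101169386, chr13:41291108-41291683 and chr2:127859242-127859618, had 187, 142 and 148 RXR tags under T0901317 in wild type. In the same order, LXR tags under T0901317 were 21.4, 85.8 and 45.0. PPARα tags there were 10.7, 10.7 and 8.58 in wild type and 34.3, 19.3 and 23.6 in LXRdKO. The shared site chr9:35112713-35113202 had 259 LXR, 429 RXR and 289 PPARα tags under vehicle. It and the shared sites chr2:98506274-98507533 and chr2:98502288-98503206 had 66.5 or more normalised tags in every transcription factor library, and without an input library they cannot be set against background. The shared sites chr1:90184549-90185070 and chr5:124676558-124676960 had 133 and 154 RXR tags under vehicle. Of the PPARα-only sites, chr10:96712432-96712748 had 118 RXR and 23.6 PPARα tags under vehicle, chr16:94671324-94671719 had 96.5 and 79.3, and chr3:131151463-131151794, chr13:94013088-94013431 and chr12:110089040-110089483 had 90.1, 114 and 94.3 RXR tags. Of the sites with neither, chr19:39182863-39183301 had 79.3 RXR tags under vehicle and 219 under bexarotene in wild type. chr15:77207919-77208284, chrX:100917826-100918161, chr11:51572766-51573136 and chr11:3062437-3063176 had 107, 90.1, 103 and 70.8 under bexarotene in wild type. The last of these had 30.0 or more normalised tags in every transcription factor library, with 72.9 for LXR under vehicle. Without an input library it cannot be set against background either.

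**Figure D1:**
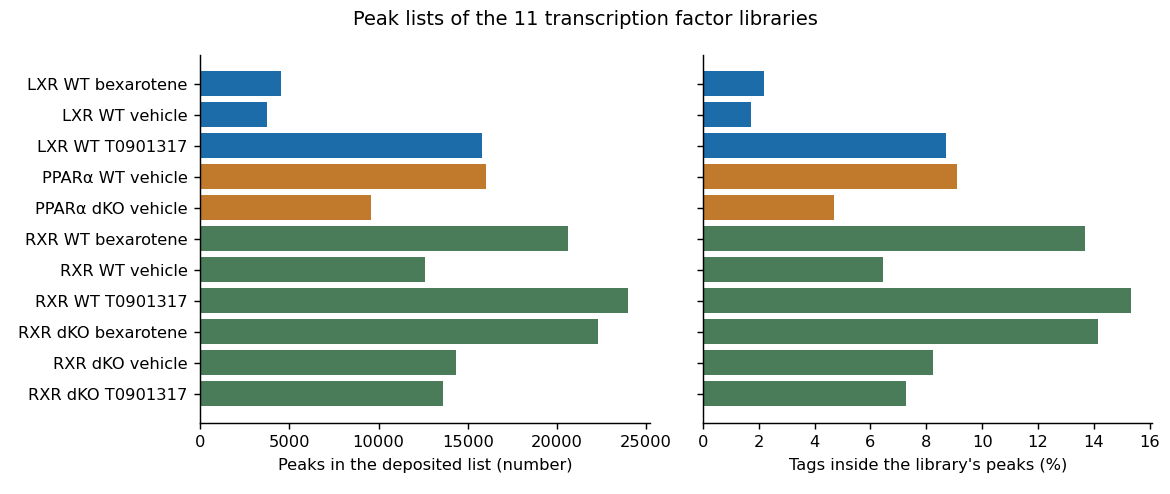
Number of peaks in the authors' list of each transcription factor library (bars), by factor, genotype and treatment. LXR had 3771 peaks under vehicle and 15782 under T0901317; RXR in LXRdKO had 14337 under vehicle and 13609 under T0901317.

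The next comparison asked whether agonists change LXR occupancy. LXR tags were higher under T0901317 than under vehicle at most LXR sites. The median log2 ratio over 16322 sites was 1.36 (quartiles 0.79 and 1.97), and the log2 ratio of summed tags was 1.33 (95% interval 1.32 to 1.35). Of 15891 sites with at least 10 normalised tags, 67.1% were at least 2-fold higher and 0.699% at least 2-fold lower. The lists hold 3771 peaks under vehicle and 15782 under T0901317, and 91.6% of vehicle peaks overlapped a T0901317 peak. LXR tags differed little between bexarotene and vehicle at the same sites, with a median of 0 and a log2 ratio of sums of 0.13 (0.11 to 0.14). LXR sites were picked largely from the T0901317 list, so the rise at them is in part set by that choice. Without that list 1160 sites were LXR only and 4629 shared, against 6650 and 9672 with it. There is no second library to set these ratios against. LXR tags were also higher under T0901317 at sites with no LXR peak, with a median of 0.66 at PPARα-only sites.

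RXR in LXRdKO against wild type asked whether RXR occupancy depends on LXR. Under vehicle, RXR tags were similar or slightly higher in LXRdKO in every class: the log2 ratio of sums was 0.11 at LXR-only sites (95% interval 0.09 to 0.13), 0.21 at shared sites, 0.24 at PPARα-only sites and 0.20 at sites with neither. Under bexarotene it was -0.10 at LXR-only sites (-0.12 to -0.09), -0.08 at shared sites, 0.10 at PPARα-only sites and 0.11 at sites with neither. Under T0901317, RXR tags were lower in LXRdKO in every class, most at LXR-only sites, with log2 ratios of sums of -1.08 (-1.10 to -1.06), -0.82, -0.61 and -0.80 in the same order. The medians over sites were -1.04, -0.79, -0.55 and -0.75. LXR-only and shared sites were picked largely from the T0901317 LXR list: without it they number 1160 and 4629, against 6650 and 9672 with it. Their ratios under vehicle and bexarotene are thus read mostly at sites without an LXR peak in those treatments. Those ratios therefore do not show whether RXR depends on LXR at sites with an LXR peak under vehicle or bexarotene. Sites with neither were picked largely by the RXR lists, so the ratio there is in part set by that choice. Of RXR peaks under T0901317, 7503 in wild type and 2744 in LXRdKO overlapped neither an LXR nor a PPARα peak. At LXR-only sites with at least 10 normalised tags, 54.0% of 5644 were at least 2-fold lower in LXRdKO and 1.19% at least 2-fold higher.

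Set against vehicle in the same genotype, RXR tags under T0901317 were higher in wild type in every class, by 1.09 on the log2 scale at LXR-only sites, 0.84 at shared sites, 0.67 at PPARα-only sites and 0.91 at sites with neither. In LXRdKO the same ratios were -0.10, -0.19, -0.18 and -0.08. Sites were then matched by ranges of raw vehicle tags, the highest open-ended, so vehicle tags can still differ between classes within a range. Matched in this way, wild-type LXR-only sites under T0901317 exceeded PPARα-only sites by 0.46 (counting SE 0.0174) and sites with neither by 0.31 (0.0143). Under bexarotene the same differences were 0.21 and 0.16 in wild type, and with 1 library per condition the spread between libraries is not known. Under bexarotene, RXR tags were higher than under vehicle in both genotypes, by 0.78, 0.80, 0.58 and 0.72 in wild type and by 0.56, 0.51, 0.44 and 0.62 in LXRdKO. The bexarotene RXR libraries have tags of 34 bp, and those of vehicle and T0901317 32 bp. The share of tags in the authors' RXR peaks was 6.46% under vehicle, 13.7% under bexarotene and 15.3% under T0901317 in wild type, and 8.22%, 14.1% and 7.27% in LXRdKO.

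**Figure D2:**
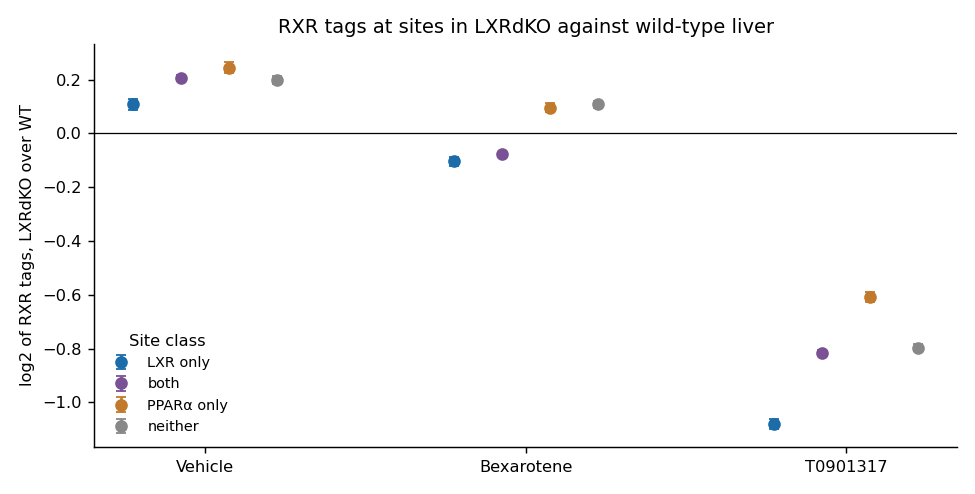
Log2 ratio of summed RXR tags, LXRdKO over wild type, for each site class (LXR only, both, PPARα only, neither) and treatment; error bars are 95% exact binomial intervals for counting error. Under T0901317 the values run from -1.08 at LXR-only sites to -0.61 at PPARα-only sites, and under vehicle from 0.11 to 0.24.

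PPARα was compared between genotypes under vehicle. PPARα tags were lower in LXRdKO both at sites with an LXR peak (median log2 ratio -0.64 over 10167 sites, ratio of sums -0.58, 95% interval -0.59 to -0.57) and without one (median -0.55 over 7405 sites, ratio of sums -0.41, -0.43 to -0.40). Of sites with at least 10 normalised tags, 3202 of 10005 with LXR and 2337 of 7272 without were at least 2-fold lower. The authors' list holds 16005 peaks in wild type and 9561 in LXRdKO, with 9.10% and 4.69% of tags in peaks, and 82.7% of LXRdKO peaks overlapped a wild-type peak. These sites were picked by PPARα peaks, more of them from wild type, so lower tags in LXRdKO are in part set by that choice. At LXR-only sites, which lack a wild-type PPARα peak, mean normalised PPARα tags were 8.72 in wild type and 7.01 in LXRdKO. At sites with neither they were 7.03 and 7.14, and some of those sites come from the LXRdKO PPARα list. Each genotype has 1 library, so how strongly each immunoprecipitation worked was not separated from genotype.

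RNAPII was used to ask which regions respond to the LXR agonist. In wild-type liver T0901317 raised RNAPII in chr19:44470001-44480000 from 5.50 and 13.2 CPM in the control replicates to 884 and 868, a log2 change of 6.66 ± 1.22 (SE, n = 2 and 2; paired edgeR fit, adjusted p = 0.000215). This bin holds 4 LXR-only sites and no PPARα peak, with PPARα profiled under vehicle only. At these sites normalised LXR tags were 0 to 4.29 under vehicle and 17.2 to 30.0 under T0901317. The neighbouring chr19:44480001-44490000 rose by 3.93 ± 0.77, and chr7:14330001-14340000, chr7:14340001-14350000 and chr7:14360001-14370000 rose by 4.05, 4.77 and 4.01. RNAPII fell in chr3:130320001-130330000 (-3.34), chr3:130330001-130340000 (-2.60), chr15:101090001-101100000 (-2.74), chr15:101100001-101110000 (-2.63) and chr19:39950001-39960000 (-2.79). The paired fit called 116 bins higher, in 47 runs of bins, and 80 lower, in 58 runs. Of these, 115 of the 116 and all 80 changed in the same direction in both replicates. Here and below, the paired fit picks bins by the agreement of the same replicates, so that agreement is largely fixed by the selection. An LXR site lay in 30 of the 116 and in 12 of the 80, and the share over all tested bins is not given here. Among only the enriched bins the paired fit called 133 higher and 84 lower. The fit without the replicate term, by edgeR's quasi-likelihood test, called 0 bins, and DESeq2 without it called 30. In that edgeR fit 3286 bins, 1.34% of those tested, had an unadjusted p under 0.05. A share of 0.05 would be met without any change, so this count lies below chance. Without wild-type control replicate 1 the paired fit called 58 higher and 9 lower, without control replicate 2 53 and 141, without T0901317 replicate 1 56 and 5, and without T0901317 replicate 2 34 and 7, so the balance of directions depends on the library.

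**Figure D3:**
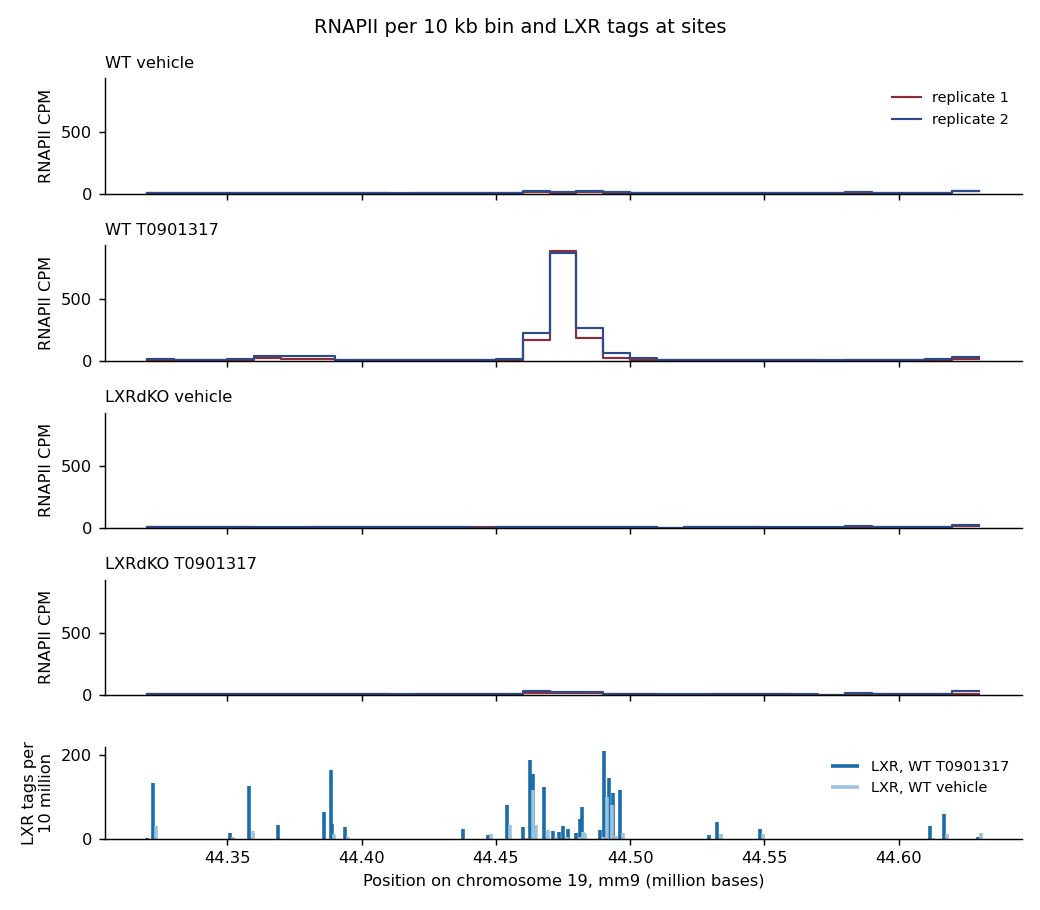
RNAPII CPM per 10 kb bin around chr19:44470001-44480000 in mm9, under vehicle and T0901317 in both genotypes (linear axis, 1 line per library). The lowest panel gives normalised LXR tags at sites in wild type under vehicle and T0901317. In the central bin both wild-type T0901317 libraries lie at 884 and 868 CPM and both LXRdKO T0901317 libraries at 14.6 and 25.7.

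In LXRdKO liver the paired fit called 15 bins higher and 17 lower under T0901317. All 15 and 15 of the 17 changed in the same direction in both replicates. An LXR site lay in 0 of the 15 and in 2 of the 17. chr5:146900001-146910000 rose by 3.95 ± 0.68, chr5:146910001-146920000 by 3.45, chr5:146920001-146930000 by 3.03, chr8:107260001-107270000 by 3.26 and chr4:60590001-60600000 by 3.40. RNAPII fell in chr12:19120001-19130000 (-2.83), chr13:52280001-52290000 (-2.65), chr13:52270001-52280000 (-2.27), chr12:16560001-16570000 (-2.50) and chr6:141650001-141660000 (-2.43). Of the 116 bins higher in wild type, 106 also had a positive log2 change in LXRdKO, 3 were called there, and 2 passed the test of a difference between genotypes. Of the 80 lower bins, 54 had a negative change in LXRdKO (median -0.27, against -1.76 in wild type), 2 were called there and 2 passed that test. Bins chosen in 1 genotype had smaller medians in the other in both directions of the comparison: 1.95 in wild type and 0.45 in LXRdKO for those 116, and 2.35 in LXRdKO and 0.91 in wild type for the 15. At chr19:44470001-44480000 the change in LXRdKO was 1.35 ± 1.02, and the difference between genotypes, -5.31 ± 1.48, did not pass the threshold (adjusted p = 0.754). Without the replicate term edgeR called 0 bins in LXRdKO, with 2581 at an unadjusted p under 0.05, and DESeq2 called 1. The paired fit called 2 higher and 4 lower without LXRdKO control replicate 1, 1 and 20 without control replicate 2, 102 and 13 without T0901317 replicate 1, and 7 and 50 without T0901317 replicate 2. DESeq2 with the replicate term called 2 higher and 9 lower. Among only the 18548 enriched bins, which include 7 of the 15 higher and 3 of the 17 lower, edgeR with that term called 0. Of these enriched bins 1413 (7.62%) had an unadjusted p under 0.05.

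The response to the RXR agonist was compared next. In wild type, bexarotene raised RNAPII in chr19:44470001-44480000 by 5.34 ± 1.15 (adjusted p = 0.00796, paired edgeR fit), to 316 and 404 CPM. chr7:14410001-14420000, chr7:14340001-14350000 and chr7:14400001-14410000 rose by 4.47, 3.99 and 3.96, and chr16:21770001-21780000 rose by 3.74 ± 0.84. The paired fit called 105 bins higher and 74 lower, and 96 and 70 of these changed in the same direction in both replicates. An LXR site lay in 31 of the 105 and in 10 of the 74. Among only the enriched bins the paired fit called 181 higher and 203 lower. The 5 lower bins with the largest fitted change, chr4:52960001-52970000, chr4:52890001-52900000, chr4:52950001-52960000, chr4:52920001-52930000 and chr4:52970001-52980000, had 0 tags in both bexarotene libraries and were at least 8.80-fold, 7.65-fold, 6.50-fold, 6.12-fold and 5.74-fold lower, against a floor of 3 counts over the group. They lie in chr4:52880001-52990000, which holds 7 of the 74 lower bins and where wild-type control replicate 1 also had 8 tags against 181 in replicate 2. Outside it, chosen after the values were seen, the lowest changes were -3.23 ± 0.64 in chr10:127430001-127440000, -3.04 in chr6:9020001-9030000, -3.01 in chr15:101100001-101110000, -3.01 in chr9:121820001-121830000 and -2.98 in chr1:95030001-95040000.

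In LXRdKO, chr19:44470001-44480000 rose by 5.26 ± 1.16 under bexarotene (adjusted p = 0.0130), close to the value in wild type, with a difference between genotypes of -0.08 ± 1.43. chr16:21770001-21780000 rose by 4.05, chr19:39380001-39390000 by 4.13, chr9:95470001-95480000 by 4.07 and chr7:26710001-26720000 by 4.00. RNAPII fell in chr8:42030001-42040000 (-3.57), chr8:42020001-42030000 (-2.99), chr15:101090001-101100000 (-2.81), chr9:46110001-46120000 (-2.64) and chr2:103270001-103280000 (-2.63). The paired fit called 105 bins higher and 100 lower, and 93 of the 105 had a positive and 68 of the 100 a negative change in wild type, where the median of those 100 was -0.23 against -1.73 in LXRdKO. All 105 and all 100 changed in the same direction in both replicates, and 20 of the 105 and 6 of the 100 held an LXR site. Among only the enriched bins the paired fit called 352 higher and 161 lower. Of the bins that rose in wild type, 102 of 105 had a positive change in LXRdKO, 21 were called in both, and 4 passed the test of a difference between genotypes. Of the 74 that fell in wild type, 68 had a negative change in LXRdKO, with a median of -0.92 against -2.20. Here too the medians were smaller in the genotype the bins were not chosen in: 1.98 in wild type and 1.15 in LXRdKO for bins that rose in wild type, and 2.04 in LXRdKO and 0.80 in wild type for those that rose in LXRdKO. Without the replicate term edgeR called 0 bins in wild type and 0 in LXRdKO, with 2961 (1.21%) and 5010 (2.04%) at an unadjusted p under 0.05. DESeq2 without that term called 44 and 84, of which 79 in LXRdKO were higher and 5 lower (191 and 47 with it). In LXRdKO the paired fit called 7 higher and 15 lower without control replicate 1, 10 and 51 without control replicate 2, 88 and 148 without bexarotene replicate 1, and 44 and 17 without bexarotene replicate 2. In wild type it called 21 and 9, 33 and 127, 32 and 14, and 81 and 13 in the same order.

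**Figure D4:**
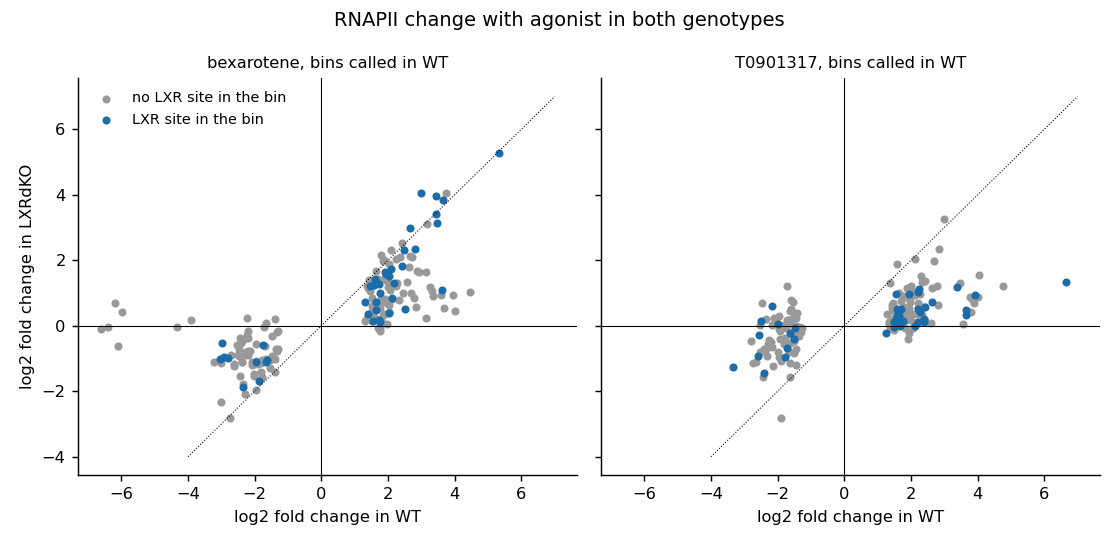
Log2 change of RNAPII in LXRdKO against that in wild type for each 10 kb bin called in wild type by the paired fit, with bexarotene and T0901317 in separate panels and bins with an LXR site marked. Of the bins higher in wild type, 102 of 105 under bexarotene and 106 of 116 under T0901317 had a positive change in LXRdKO; of the lower bins, 68 of 74 and 54 of 80 had a negative one.

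RNAPII in LXRdKO against wild type under vehicle differed in 38 higher and 21 lower bins in the paired fit. Higher in LXRdKO were chr7:37950001-37960000 by 3.10 ± 0.42, chr7:37940001-37950000 by 3.08, chr7:37930001-37940000 by 2.52, chr7:14340001-14350000 by 2.65 and chr7:14410001-14420000 by 2.51. Lower in LXRdKO were chr4:60590001-60600000 (-3.48), chr4:61430001-61440000 (-2.97), chr10:92960001-92970000 (-2.96), chr6:121960001-121970000 (-3.30) and chr6:122090001-122100000 (-2.70). At chr6:121960001-121970000 the libraries of replicate 2 had 0 to 0.215 CPM and those of replicate 1 had 4.51 to 52.3, so the difference rests on replicate 1. Without the replicate term edgeR called 0 bins, with 3143 (1.28%) at an unadjusted p under 0.05, and DESeq2 called 0. The balance of directions was not stable: the paired fit called 8 higher and 4 lower without wild-type control replicate 1, 47 and 157 without replicate 2, 11 and 1 without LXRdKO control replicate 1, and 30 and 9 without replicate 2. DESeq2 with the replicate term called 9 higher and 20 lower. Among only the enriched bins, which include 7 of the 38 and 3 of the 21, edgeR with that term called 4 higher and 1 lower. With loess offsets it called 0, with 1693 (9.13% of enriched bins) at an unadjusted p under 0.05.

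Differences between genotypes in the response to an agonist were tested as interactions. The paired fit called 2 bins higher and 9 lower for bexarotene, and 6 higher and 2 lower for T0901317. Without the replicate term edgeR called 0 and 0, with 3037 (1.24%) and 2593 (1.06%) at an unadjusted p under 0.05, and DESeq2 called 0 and 1. With the replicate term DESeq2 called 0 for bexarotene, with 2076 (0.847%) at an unadjusted p under 0.05, and 3 higher and 2 lower for T0901317. Among only the enriched bins, which include 2 of the 11 and 1 of the 8, edgeR with that term called 0 and 0. Of the enriched bins 1156 (6.23%) and 1842 (9.93%) had an unadjusted p under 0.05. Both higher bins for bexarotene lie in chr4:52880001-52990000. Leaving out 1 library gave paired counts of 3 to 49 for bexarotene and of 0 to 125 for T0901317. The highest were 32 higher and 17 lower without wild-type control replicate 2, and 110 higher and 15 lower without LXRdKO T0901317 replicate 1.

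Enriched bins with the 300 strongest LXR peaks under T0901317, 163 in number, lay higher under T0901317 in wild type, with a median log2 change of 0.25 and 72.4% above 0. In camera without the replicate term, adjusted p was 4.28e-06 with the preset correlation and 0.0418 with an estimated one. In camera on the paired fit of only the enriched bins, which called 217 bins, adjusted p was 3.61e-06 and 0.0876. Enriched bins without a site also passed without the replicate term (median 0.07, adjusted p = 0.00545 and 0.0418). In LXRdKO the median of the LXR set was 0.04, and the difference between genotypes was -0.25 (adjusted p = 0.000250, and 0.0662 with an estimated correlation). Enriched bins with the strongest PPARα peaks, 195 in number with 26 shared, had a median of 0.25 under bexarotene in wild type (adjusted p = 6.56e-07, and 0.318 with an estimated correlation) and of 0.30 in LXRdKO (4.63e-07, and 0.296); within replicates 1 and 2 it was -0.09 and 0.71 in wild type and 0.56 and 0.21 in LXRdKO. Within replicates the wild-type T0901317 median of the LXR set was -0.37 in replicate 1 and 0.48 in replicate 2, and that of enriched bins without a site -0.44 and 0.22.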

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

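The test on missing DNA was written before the values it measures were seen, and the other tests of explanations in this part were chosen only after the result was seen. The bins below had a response to an agonist that differed between genotypes in the edgeR fit with the replicate number as a term, at an adjusted p under 0.05 by the interaction; without that term 0 bins passed, and the paired fit called 11 for bexarotene and 8 for T0901317. These calls depend on the tool: DESeq2 with the same term called 0 for bexarotene and 5 for T0901317, and edgeR with it among only the enriched bins, which include 2 of the 11 and 1 of the 8, called 0 and 0. Values are log2 changes in LXRdKO minus those in wild type.

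For bexarotene, chr4:52950001-52960000 differed by 6.86 and chr4:52960001-52970000 by 6.50; both wild-type bexarotene libraries had 0 tags there, so these fitted values are no bounds. chr7:14340001-14350000 differed by -3.54 (3.99 in wild type, 0.45 in LXRdKO), chr7:14410001-14420000 by -3.44, chr7:14400001-14410000 by -3.01 and chr7:14370001-14380000 by -2.88. In these bins both control libraries of wild type lay at 0.458 to 2.09 CPM. chr9:46110001-46120000 differed by -2.57, with a change of -0.07 in wild type and -2.64 in LXRdKO. For T0901317, chr4:60590001-60600000 differed by 3.87, chr7:4400001-4410000 by 2.92, chr19:40130001-40140000 by 2.63, chr1:87910001-87920000 by 2.41 and chr11:120590001-120600000 by 2.29. chr7:14340001-14350000 differed by -3.54 and chr7:14400001-14410000 by -3.38 for T0901317. The differences for both agonists rest on the same control libraries, so a bin that meets both is not a second finding, and LXRdKO already differed from wild type under vehicle by 2.65 in chr7:14340001-14350000 and by -3.48 in chr4:60590001-60600000. Counts without 1 library ran from 3 to 49 for bexarotene and 0 to 125 for T0901317.

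The segment chr4:52880001-52990000 is the longest run of 10 kb bins, 11 of them, in which wild-type bexarotene RNAPII libraries hold under 25% of the tags that the wild-type T0901317 libraries predict; the next longest has 6. Missing DNA in some of the mice may account for it: of the 11 transcription factor libraries, 4 had under 25% of the tag density of the 100 kb before the segment, the lowest 0% in wild-type PPARα, and 3 RNAPII libraries did. These 7 libraries are all wild type and hold at most 8.52% of the flanking density, and the other 16 hold 80.9% or more. Tag length as the cause is argued against by libraries of 32 bp tags, which differ by 120 percentage points. If DNA is missing, wild-type control RNAPII replicates 1 (5.55%) and 2 (97.9%) come from different mice, which the segment leaves open for the other pairs of replicates, and a change of RNAPII is not needed to account for the lower bins there.

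RXR tags were higher under T0901317 in wild type in all site classes and not in LXRdKO, with 1 library per condition, so counting error is the only spread known. Within matched ranges of vehicle tags, wild-type LXR-only sites under T0901317 exceeded PPARα-only sites by 0.46 and sites with neither by 0.31. In LXRdKO under T0901317 these differences were 0.01 and 0.02. Under bexarotene they were 0.21 and 0.16 in wild type and 0.08 and -0.01 in LXRdKO. Every class was then taken from the vehicle and bexarotene LXR lists, at sites with an RXR peak under vehicle. The differences were 0.24 and 0.38 in wild type under T0901317. They were 0.16 and 0.31 in LXRdKO under T0901317, which lacks LXR by the labels. Stronger enrichment of that library and the picking of LXR sites from the T0901317 list therefore cannot be told apart from an effect of LXR as the source of the excess at LXR-only sites. The difference from vehicle shared by all classes, 0.67 at PPARα-only sites, 0.84 at shared sites and 0.91 at sites with neither, cannot be told apart from stronger enrichment either.

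RXR tags were higher under bexarotene in both genotypes. Repeated tags at 1 position are argued against as the cause, since with at most 1 tag per position the log2 ratio of sums at LXR-only sites in wild type was 0.77. A difference between sequencing runs cannot be told apart from bexarotene, because 0 control RXR libraries have the tag length of the bexarotene libraries. A biological effect of the agonist stays open as well.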

How the results depend on the processing

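Counts below are RNAPII bins called for bexarotene and T0901317 in wild type, for bexarotene and T0901317 in LXRdKO, for LXRdKO against wild type under vehicle, and for the genotype difference in the bexarotene and T0901317 responses, in this order. Named bins and their log2 changes above come from the paired fit. The fit without the replicate term, fixed before the data were examined, calls 0 in all 7. It also calls 0 with RLE size factors, no low-count filter, 1 tag per position, 5 kb bins and each library left out. With the replicate block it calls 179, 196, 205, 32, 59, 11 and 8; with DESeq2 44, 30, 84, 1, 0, 0 and 1; with only the groups compared 2, 10, 12, 0, 3, 0 and 0. These alternatives were planned; the following were chosen after seeing the data. The block with DESeq2 gives 185, 157, 238, 11, 29, 0 and 5; the block with 1 tag per position 187, 198, 220, 33, 53, 11 and 11. Only enriched bins give 69, 63, 75, 0, 0, 0 and 0, with the block 384, 217, 513, 0, 5, 0 and 0. Only enriched bins with loess offsets give 78, 65, 85, 0, 0, 0 and 0, with the block 380, 249, 505, 0, 0, 0 and 0. With the block and 1 library left out the counts run from 30 to 160, 41 to 194, 22 to 236, 6 to 115, 12 to 204, 3 to 49 and 0 to 125; a group left with 1 library is assumed to vary like the others.

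The share of LXR peaks on RXR peaks was 74.5% with centres within 100 bp, 78.3% for peaks above the median score and 44.5% for the 2000 strongest; of LXR peaks on PPARα peaks 68.6%, 73.3% and 38.3%; and of RXR peaks on PPARα peaks 58.2%, 63.3% and 44.2%. The median log2 ratio of RXR at LXR-only sites, LXRdKO over wild type, was under vehicle 0.0300 when scaled by tags outside sites, 0.10 in a 400 bp window and 0.16 at sites with at least 10 normalised tags. Under bexarotene it was -0.0270 in the wide window and -0.11 at those sites. Under T0901317 it was -1.17, -0.95 and -1.11, and -0.97 with tags shifted by 60 bp, a setting chosen after seeing the data; it stayed below 0 in all 24 combinations of class and setting. The PPARα median at sites with LXR was -0.71 when scaled by tags outside sites, -0.70 in the wide window and -0.74 with shifted tags, and at sites without LXR -0.62, -0.65 and -0.68. The LXR median under bexarotene was 0.14 in the wide window and 0.0536 with shifted tags, and under T0901317 1.47 when scaled by tags outside sites, 1.34 and 1.43. The cause of these shifts was not tested.

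Steps foreseen on gene lists, gene bodies and promoters, gene panels, genes near sites, DR1 and DR4 sequences and cell type markers were not run, because no annotation or sequence of mm9 was used here. With 2 libraries per group the fit without the block recovered 0 of 66 simulated 8-fold changes, in counts drawn from the paired fit. Its count of 0 therefore does not show that RNAPII was unchanged.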

Other observations

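The test of the relation between RXR and RNAPII was written before its result was seen, and the search for windows without tags was chosen after the segment on chromosome 4 was found. LXR peaks surround the bin with the largest RNAPII response to T0901317. At the LXR-only site chr19:44388789-44389205 normalised LXR tags were 10.7 under vehicle and 165 under T0901317, and RXR tags in wild type 6.43 and 62.2. At chr19:44468321-44468976 RXR tags were 6.43 under vehicle, 92.2 under T0901317 and 87.9 under bexarotene in wild type, and 4.29, 10.7 and 10.7 in LXRdKO. RNAPII in chr19:44470001-44480000 rose under bexarotene in LXRdKO, to 143 and 505 CPM. RXR tags in LXRdKO under vehicle and bexarotene were 68.6 and 124 at the shared site chr19:44462921-44463776, 17.2 and 53.6 at the LXR-only site chr19:44464097-44464542 and 6.43 and 38.6 at the LXR-only site chr19:44322536-44323170. They were 6.43 and 4.29 at chr19:44388789-44389205, and at the 4 LXR-only sites inside the bin they were 0 and 0, 0 and 4.29, 0 and 0, and 4.29 and 0. These sites were chosen after their values were seen.

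A hypothesis was that bins which gain RXR also gain RNAPII. The change in RXR was set against that in RNAPII over enriched bins with sites and at least 20 RXR tags at them in the 2 libraries together. RNAPII changes came from the fit with the replicate number as a term. Under T0901317 the Spearman coefficient was 0.191 over 6136 such bins in wild type and 0.0374 over 5304 in LXRdKO, as predicted for T0901317. Under bexarotene it was 0.189 in wild type and 0.0998 in LXRdKO. Bins are not independent replicates, each RXR condition has 1 library, and the difference between genotypes was not tested. From vehicle to T0901317 the share of tags in RXR peaks went from 6.46% to 15.3% in wild type and from 8.22% to 7.27% in LXRdKO. The lower coefficient in LXRdKO under T0901317 therefore cannot be told apart from that difference in enrichment.

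Windows of 2 kb with tags in wild type and at most 5% of the expected tags in LXRdKO were searched across 13 wild-type and 10 LXRdKO libraries. With at least 200 wild-type tags, 0 of 51439 windows met this; after this result the minimum was lowered to 40, and 1 of 697717 did, chr2:101246001-101248000, with 42 tags in wild type and 0 in LXRdKO where 33.1 were expected. The reverse search found 0 windows at either minimum. A deletion shorter than a window would be missed.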
